A study of Danio rerio with 12 samples.

How the data were processed

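Messenger RNA levels were measured by RNA sequencing in pools of zebrafish embryos at 10 somites. Per the labels, control or pbx2/4 morpholinos were injected into eggs of 1 cell, RNA came from single embryos, and it was pooled by group once the genotypes were known. The labels give 4 groups of 3 libraries and describe separate rounds of egg collection and injection, so the spread between libraries of a group includes biological variation between rounds.

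The authors deposited a table of 12 count columns over 31051 gene identifiers, with a gene name beside each identifier. The deposited values are estimated counts, not normalised: 13.7% of them were not whole numbers (tolerance 1e-06), so reads appear to have been divided among genes, and 22.5% of the genes tested held such a value in at least 1 library. They were rounded to whole numbers before testing. The design written before the data were examined assumed whole counts, and the same test was used on the rounded values. TopHat 1.4, edgeR and the Zv9 genome build are named in the submitters' processing notes. How reads were assigned to genes, the annotation release, and the type and strand setting of the library kit are not given in the sources used here, so overlapping and antisense genes cannot be separated. The authors also deposited 3 tables of their own comparisons against control, each with an unadjusted p-value and a log fold change per gene, whose base is not given in the sources used here. After their sign was reversed, they had a slope of 1.005 to 1.009 on the log2 fold changes computed here, where natural logarithms would give 0.693, so the deposited values were read as log2. They run from the treated group to control, opposite in sign to those given here, and correlated across genes at 0.993 to 0.996 after the reversal, where genes are not independent replicates.

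The count columns carry group words but no replicate number, so each column was assigned to a group and not to a numbered replicate. In 4 columns the group was read from a W for wild type and an M for mutant at prdm1, with or without the word pbx. The columns fall into 3 sets by the form of their names, called sets A, B and C here, and each set holds 1 library of each group. In a test of pairing, computed in the same run as the first counts of calls, deviations from the group mean correlated across genes at 0.45 to 0.67 for the 18 pairs of libraries from the same set, and at -0.48 to -0.03 for the 36 pairs from different sets. The pairing thus comes from the column names and the values, and the labels do not say what a set stands for. The set was used as the block wherever a block is named, and its values are given beside those named genes and lists of the text whose call they change or whose count they move by over 1.5 times. Some column names of the same group share a sample number across sets. The smallest chi-square per gene between libraries of the same group was 12.2, far above sampling noise, and no libraries were merged. This value argues against repeat sequencing of the same library. It cannot exclude separate libraries made from the same RNA pool.

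Differential expression was tested with quasi-likelihood F tests of edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr by group and all 12 libraries in a single model of the 4 groups without a block, which left 8 residual degrees of freedom. The filter kept 18117 genes. P-values were adjusted by the Benjamini-Hochberg method, and genes were called at an adjusted p under 0.05. Unless another method is named, adjusted p-values are from this test. Standard errors are the absolute log2 fold change divided by the square root of F. Levels are CPM (normalised read counts) on TMM-scaled library sizes, with the standard deviation (SD) over the 3 libraries of a group. The biological coefficient of variation was 0.212 without the block and 0.075 with it. A value of 1 count corresponded to 0.058 to 0.11 CPM. The interaction contrast was the effect of prdm1 loss in pbx2/4 morphants minus that in controls. Total counts were 9059663 to 17236848 per library, and intervals from counts cover counting error only.

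There were 27 gene lists, fixed before the data were examined. They cover fast muscle, slow muscle, pan-muscle sarcomere and contraction, myogenic regulators, tailbud and segmentation clock, notochord and floor plate, neural crest, Rohon-Beard and sensory neurons, neural progenitor and hindbrain patterning, Hox paralog groups 1 to 4, Hox paralog groups 5 to 13, forebrain with midbrain and eye, otic and other placodes, hatching gland, blood, endothelium, heart field, endoderm and pancreas, Hedgehog targets, FGF targets, the retinoic acid pathway, p53 and DNA damage response, interferon and innate response, ribosomal proteins, cell cycle, epidermis and periderm, and reference genes. Each list was tested with camera from limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01) in 6 contrasts, and p-values were adjusted over the 162 tests. Camera with an estimated correlation, camera with the block and fry were run beside it. With the preset correlation 52 tests passed, and with an estimated correlation 7 did: slow muscle and the Rohon-Beard list for prdm1 loss with and without pbx2/4 morpholinos, and the hindbrain list in pbx2/4 morphants against control and in double embryos against control and against prdm1 mutants. With both the block and an estimated correlation 2 of the 162 tests passed, those of the Rohon-Beard list for prdm1 loss with and without pbx2/4 morpholinos (adjusted p = 0.0209 in both). List members were matched by symbol. Gene names came from the count table, 20486 identifiers were also in the reference table of gene names, and a RefSeq gene table of another assembly served only for names and for which genes neighbour each other. The files give no coordinates, so none are given.

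Genes named in the text were chosen by a rule set before the data were examined. It took the prdm1 and pbx genes whatever their result. For the comparisons against control and the interaction it took up to 8 genes of largest rise and 8 of largest fall among called genes with a symbol, a mean log2 CPM of at least 1 and no overlap between libraries of the groups. Clone-based names were not counted as symbols. Complete separation of 3 against 3 libraries arises by chance in 10% of genes. From each list it took up to 4 called members by smallest adjusted p, or the member of smallest p where none was called, and for the fast and slow muscle lists every called member. Members of the fast myosin heavy chain family (myhz1.1, myhz1.2, myhz1.3, myhz2, myhc4) and the slow family (smyhc1, smyhc2, smyhc3) held fractional counts in most libraries and lie among near-identical copies, so their single values are uncertain and the summed families were also tested.

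The code was tested on simulated data with 200 of 18117 genes changed, 100 by each fold. The data were made from the library sizes and from the means, set effects and gene-wise spread of the fit with the block. The higher recovery with the block is therefore built into the simulation and does not show that this fit suits the real data better. For prdm1 mutants against controls, the fit without the block recovered 40% of 2-fold changes and 81% of 4-fold changes with 0 false calls, and the fit with the block recovered 70% and 96% with 7 false calls. For pbx2/4 morphants against controls these shares were 36% and 80% without the block, and 76% and 95% with it, with 0 and 6 false calls. For double embryos against controls they were 32% and 74% without the block, and 61% and 90% with it, with 0 and 14 false calls. Alternatives were RLE scaling, library size alone, DESeq2 1.42.0, edgeR's likelihood ratio test, no filter, a filter of 1 CPM in at least 3 libraries, the block, only the 6 libraries compared, and each library left out. Leaving out all 4 libraries of a set, counts without rounding, the block with DESeq2, and the block with a fold change of at least 1.5 were added after the data had been seen. Gene calls with libraries left out came from the fit without the block, which ignores the pairing by set.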

Results

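Zebrafish embryos of the AB strain were profiled by RNA sequencing at 10 somites, a stage at which the first trunk muscle fibres differentiate. The 4 groups crossed prdm1 genotype with morpholino injection. Morpholinos are antisense oligonucleotides that block translation or splicing of an RNA. Controls were prdm1+/+ embryos with a control morpholino, and prdm1 mutants were prdm1-/- embryos with it. The pbx2/4 morphants were prdm1+/+ embryos with morpholinos against pbx2 and pbx4, and double embryos were prdm1-/- embryos with the pbx2/4 morpholinos. prdm1a encodes a zinc-finger repressor needed for the slow muscle fate, and pbx2 and pbx4 encode homeodomain proteins that act as partners of Hox and myogenic factors. Each group had 3 libraries, 12 in all. Estimated counts totalled 9703947 to 12510949 per library in column-name set A, 9059663 to 10288335 in set B and 15164400 to 17236848 in set C. Each set held 1 library of each group. Values with the block are from the fit with the set as a term. The first principal component, with 31.9% of the variance, parted set B from the others. The second, with 21.8%, parted embryos with pbx2/4 morpholinos from those without, and the fourth, with 9.2%, parted the prdm1 genotypes.

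The targeted genes were examined first, in every library. prdm1a (ENSDARG00000002445) RNA was 105 ± 9.4 CPM in controls (SD, n = 3), 139 ± 6.09 in prdm1 mutants, 122 ± 10.7 in pbx2/4 morphants and 227 ± 10.6 in double embryos. It was higher in double embryos than in controls by 1.12 on the log2 scale (SE 0.11, edgeR adjusted p = 0.000224), with 238.8, 218 and 225.1 CPM in the 3 double libraries against 94.8 to 113.5 in controls. Its log2 fold change in prdm1 mutants was 0.41 (adjusted p = 0.513, 0.00169 with the block), and 0.31 to 0.48 within the 3 sets. pbx2 (ENSDARG00000019717) rose from 57.1 ± 12.7 CPM in controls to 260 ± 35.5 in pbx2/4 morphants, by 2.19 on the log2 scale (SE 0.21, adjusted p = 0.00105), and its range of 225.1 to 315.6 CPM over the 6 libraries with pbx2/4 morpholinos lay above the 43.1 to 67.7 CPM of the other 6. pbx4 (ENSDARG00000052150) had 330 ± 39.7 CPM in controls and 438 ± 43.2 in pbx2/4 morphants, a log2 fold change of 0.41 (adjusted p = 0.273, 0.000103 with the block). The mutant allele is not named in the labels and morpholinos act on translation or splicing, so these RNA levels do not measure the loss of either protein. prdm1b (ENSDARG00000053592), a paralog of prdm1a, rose from 1.68 ± 0.569 CPM in controls to 7.02 ± 2.55 in double embryos (log2 fold change 2.04, SE 0.33, adjusted p = 0.007). It had 2.93 ± 0.475 CPM in prdm1 mutants and 4.695 ± 0.811 in pbx2/4 morphants. The morphants had adjusted p = 0.0548 against controls, with a call in 6 of 20 alternative settings. The second identifier named prdm1b (ENSDARG00000078168) had 2.79 ± 0.354 CPM in controls and 1.61 ± 0.802 in double embryos. pbx1a (ENSDARG00000089550) had 10.3 ± 4.31 CPM in controls and 13.8 ± 3.01 in pbx2/4 morphants (adjusted p = 0.777, 0.0429 with the block, the 1 of 20 alternative settings that called it). The second identifier named pbx1a (ENSDARG00000089610) had 0.822 ± 0.463 and 0.92 ± 0.0785 CPM in these groups (adjusted p = 0.945). In the same groups pbx3b had 3.54 ± 1.22 and 2.92 ± 0.144. prdm1c and pbx3a, at 0.318 and 0.0553 CPM in controls, were below the filter. pbx1b was not analysed here.

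**Figure D1:**
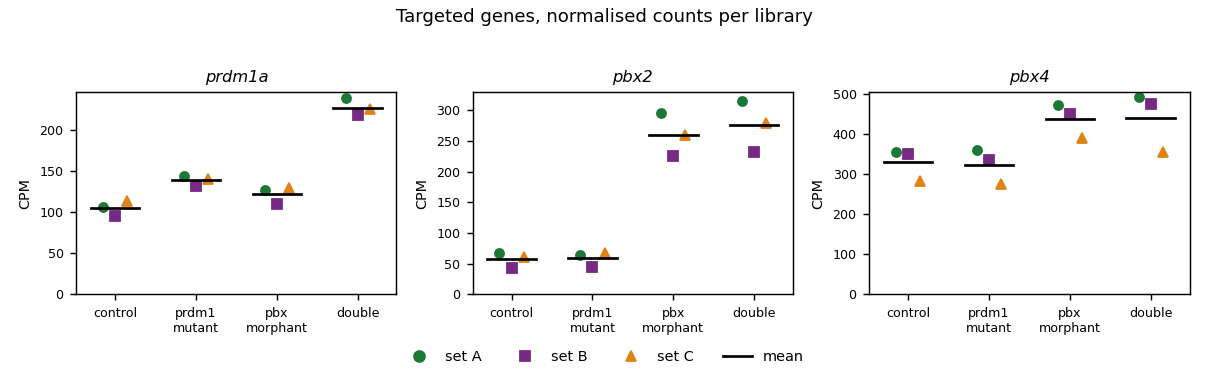
Normalised counts (CPM) of prdm1a, pbx2 and pbx4 in each of the 12 libraries, by group on the x axis and on a linear y axis, with point shape and colour for the column-name set and a line at the mean of 3 libraries. The 3 double libraries lie at 218 CPM or above for prdm1a, and the 6 libraries with pbx2/4 morpholinos at 225.1 CPM or above for pbx2.

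The comparison of prdm1 mutants with controls asked what loss of prdm1 changes in embryos with the control morpholino. Slow muscle myosin heavy chain RNA fell and fast muscle myosin heavy chain RNA rose. The 3 slow myosin heavy chain genes smyhc1, smyhc2 and smyhc3, summed, fell from 559 ± 101 CPM in controls to 141 ± 50.4 in mutants (SD, n = 3), by 1.99 on the log2 scale (SE 0.27, edgeR adjusted p = 0.00891). The 5 fast myosin heavy chain genes, summed, rose from 0.626 ± 0.358 to 26 ± 9.56 CPM, a 41.6-fold rise (log2 fold change 5.38, SE 0.47, adjusted p = 0.000335), from 3 to 10 counts per control library to 183 to 558 per mutant library. The fast myosin light chain genes myl1 and mylz2 rose by 2.34 (SE 0.28) and 2.19 (SE 0.34) on the log2 scale. Outside muscle, agr2 (ENSDARG00000070480), which encodes a disulfide isomerase of secretory cells, rose from 3.58 ± 1.07 to 139 ± 60.8 CPM (log2 fold change 5.25, SE 0.44, adjusted p = 0.000335), with 4.40 to 5.66 within the 3 sets.

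Of the 25 fast muscle genes tested, 6 rose and 0 fell (8 and 0 adjusted over the list alone). They were myhz1.1, myhz1.2, myhz1.3, myhz2, myl1 and mylz2. The list's median log2 fold change was 0.04 and its mean 1.16. It passed camera (adjusted p = 1.52e-09) but not with an estimated correlation (adjusted p = 0.0532). myhz1.1 and myhz1.2 had 1 count each over the 3 control libraries and 89 and 90 over the mutant libraries. The ratios were 83.7 (95% exact interval 14.6 to 3340) and 84.6 (14.8 to 3380). Reads shared within the family left single members uncertain. Of 15 slow muscle genes, 4 fell and 0 rose (7 and 1 adjusted over the list alone, 5 and 1 with the block), with camera adjusted p = 1.07e-12. With an estimated correlation the list had adjusted p = 0.0291 without the block but 0.379 with it. The 3 smyhc genes were joined by tnnt2c, a troponin T gene, at -0.98 (SE 0.16, adjusted p = 0.032). Of 40 pan-muscle genes, 1 fell and 0 rose (3 and 1 adjusted over the list alone, 4 and 1 with the block). Without the block this was xirp1, which encodes an actin-binding protein of myotendinous junctions, at -1.08. The list passed camera (adjusted p = 2.47e-05) but not with an estimated correlation (adjusted p = 0.423). Of 23 myogenic regulators, 1 fell and 0 rose (1 and 0 adjusted over the list alone). This was myf6, a myogenic bHLH factor gene, with 37 counts in controls and 2 in mutants (ratio 0.0508, 95% exact interval 0.00594 to 0.197), and the list did not pass camera (adjusted p = 0.112).

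In the nervous system, isl1, a LIM homeodomain gene of primary neurons, fell from 21 to 9.27 CPM (log2 fold change -1.19, SE 0.15, adjusted p = 0.00656), with -1.42 to -0.86 within the sets. It was the called member among 19 Rohon-Beard and sensory neuron genes, of which 1 fell and 0 rose (8 and 0 adjusted over the list alone, 6 and 0 with the block). The list's median was -0.45, with camera adjusted p = 4.12e-18 and, with an estimated correlation, adjusted p = 0.012 (0.0209 with the block as well). isl1 was also the member that fell in the heart field list (1 of 16 members fell, 1 adjusted over the list alone) and in the endoderm and pancreas list (1 of 14, 1 adjusted over the list alone). foxg1a, a telencephalic transcription factor gene, was the 1 of 28 forebrain, midbrain and eye genes called, at -0.74 (SE 0.13, adjusted p = 0.0388, 1 adjusted over the list alone). Camera passed the heart field (adjusted p = 0.00942), endoderm (0.0282), neural crest (0.00147), endothelium (0.0184) and FGF target (0.00186) lists in the downward direction with medians of -0.09, -0.10, -0.19, -0.13 and -0.11. None of these held with an estimated correlation (adjusted p = 0.262, 0.423, 0.0651, 0.639 and 0.0651, in that order), and endoderm also failed with the block (adjusted p = 0.0538). Of 17 neural crest genes 0 were called (1 lower adjusted over the list alone, 3 lower with the block).

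Other genes with large changes included p2rx1, an ATP-gated ion channel gene, at 4.35 (0.281 to 5.65 CPM), nme4, a nucleoside diphosphate kinase gene, at 2.94, and acp5a, an acid phosphatase gene, at 0.79 (374 to 646 CPM). Genes that fell included MYL4, a myosin light chain gene, by 1.94 on the log2 scale, TNS1, a tensin gene, at -1.58, slc4a4a, a bicarbonate cotransporter gene, at -1.48 (SE 0.13, adjusted p = 0.000378), ELOVL4 at -1.48 and SOAT2 at -1.39. agr2 was also the 1 of 12 hatching gland genes called (1 higher and 1 lower adjusted over the list alone), and that list, opposite to agr2, passed camera in the downward direction only with the block (adjusted p = 0.0494, 1 higher and 3 lower with the block). With an estimated correlation it did not pass (adjusted p = 0.89, 0.536 with the block). The Hedgehog target list passed only with the block as well (adjusted p = 0.0163, 0 of 15 called), and not with an estimated correlation (adjusted p = 0.633, 0.612 with the block). No member was called among the hindbrain, Hox 1 to 4, Hox 5 to 13, p53, ribosomal protein or cell cycle lists, whose medians were 0.04, 0.06, -0.01, -0.01, -0.03 and 0.01. In all, 35 genes were called in edgeR's test, 15 higher and 20 lower, of 18117, and 199 (89 higher, 110 lower) were called with the block. Without the control of set A, B or C the count was 17, 23 and 14, and without the mutant of set A, B or C it was 20, 23 and 22. Of the 24 named genes called, agr2, p2rx1, myhz1.3, myl1, smyhc2, smyhc3, slc4a4a and isl1, 8 in all, kept their call without each of the 6 libraries. The call of mylz2, acp5a, ELOVL4, SOAT2, tnnt2c, myf6 and foxg1a was lost whichever library was left out, with an adjusted p of up to 0.293. These fits had no block, and all 24 kept their call with the block fitted to all 12 libraries. nme4 kept it only without the mutant of set B, TNS1 only without the mutant of set C and xirp1 only without the control of set B. myhz1.2 lost its call without any 1 control, MYL4 and myhz1.1 without the control of set A or C, and smyhc1 and myhz2 without the control of set C.

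**Figure D2:**
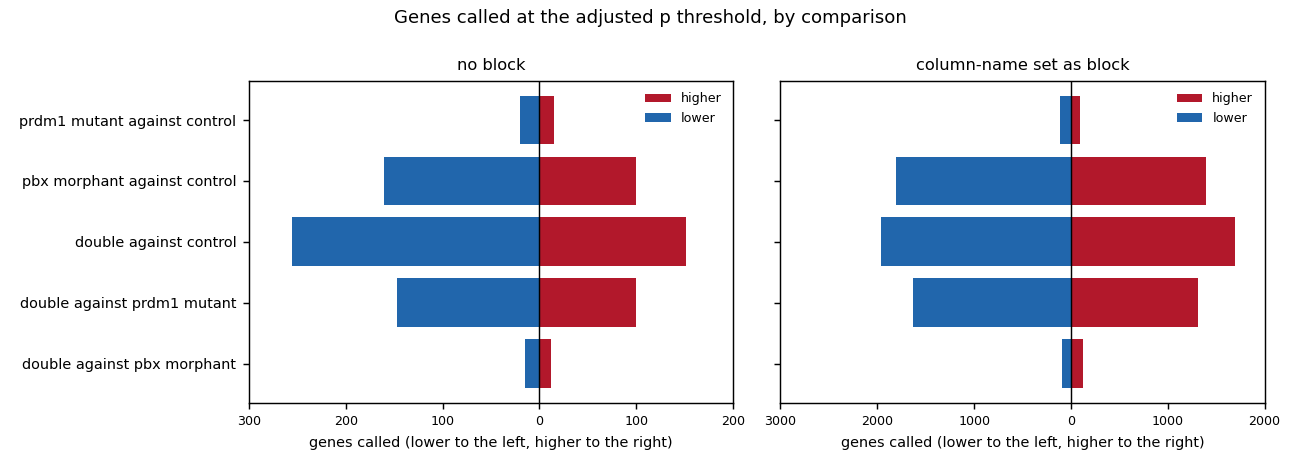
Number of genes called at an adjusted p under 0.05 on the x axis for 5 comparisons, drawn to the right for higher and to the left for lower, in edgeR's test without a block (first panel) and with the column-name set as block (second panel). The axes of the panels differ in scale: the count for pbx2/4 morphants against controls is 260 without the block and 3203 with it.

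The comparison of pbx2/4 morphants with controls asked what the pbx2/4 morpholinos change in prdm1+/+ embryos. Among the genes that fell were some of hindbrain patterning and of muscle, and among those that rose some p53-responsive genes. egr2b, a zinc-finger gene of rhombomeres 3 and 5, fell from 54.8 to 1.27 CPM (log2 fold change -5.34, SE 0.59, edgeR adjusted p = 0.00168), with -7.66 to -4.76 within the 3 sets. mafba, a segmental hindbrain bZIP gene, fell from 59.7 to 10.8 CPM (log2 fold change -2.46, SE 0.28). In muscle, srl, which encodes the sarcoplasmic reticulum protein sarcalumenin, fell from 24.6 to 7.9 CPM (log2 fold change -1.65, SE 0.23, adjusted p = 0.00433), and atp2a1, the fast muscle calcium pump gene, from 19.7 to 4.84 CPM (log2 fold change -2.04, SE 0.27, adjusted p = 0.00416). mdm2, a target and regulator of p53, rose from 97.6 to 295 CPM (log2 fold change 1.60, SE 0.26, adjusted p = 0.00967).

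Of 37 genes of neural progenitors and hindbrain patterning, 9 fell and 0 rose (17 and 1 adjusted over the list alone, 20 and 1 with the block), with camera adjusted p = 6.98e-14. With an estimated correlation the list had adjusted p = 0.00824 without the block but 0.0763 with it. cyp26b1, a retinoic acid hydroxylase gene, fell by 3.30 on the log2 scale and dbx1b, a homeobox gene of neural progenitors, by 1.45. Of 14 Hox genes of paralog groups 1 to 4, 5 fell and 0 rose (8 and 0 adjusted over the list alone, 9 and 0 with the block), among them hoxa3a at -1.12 (SE 0.13), hoxa2b at -1.24, hoxb2a at -1.28 and hoxc1a at -1.01. The list passed camera (adjusted p = 6.17e-10) but not with an estimated correlation (adjusted p = 0.0543). Of 30 Hox genes of groups 5 to 13, 0 were called (0 adjusted over the list alone, 3 higher and 2 lower with the block). The median was 0.01, and hoxd9a, the member of smallest p, had 0.58 (adjusted p = 0.0779, 0.000392 with the block). Of 14 retinoic acid pathway genes, 2 fell and 0 rose (5 and 0 adjusted over the list alone, 5 and 2 with the block), cyp26b1 and cyp26c1, the latter at -1.34. Camera passed it (adjusted p = 0.00602) but not with an estimated correlation (adjusted p = 0.0786). Of 28 forebrain, midbrain and eye genes, 5 fell and 0 rose (8 and 1 adjusted over the list alone, 12 and 4 with the block). The eye field and retina genes rx1 and pax6a had -1.28 and -0.94, and pax2a of the midbrain-hindbrain boundary -0.65. Camera passed this list (adjusted p = 0.000212) but not with an estimated correlation (adjusted p = 0.0641).

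Of 25 fast muscle genes, 2 fell and 0 rose, srl and atp2a1 (5 and 0 adjusted over the list alone, 9 and 3 with the block), and the list did not pass camera (adjusted p = 0.0737). myl1 had -1.07 and mylz2 -1.72, called only with the block and named here after their values were seen. Of 15 slow muscle genes, tnni1b, a troponin I gene, fell by 2.52 on the log2 scale and a gene named MYH7B, of a slow or cardiac myosin heavy chain, rose by 1.21 (2 higher and 2 lower adjusted over the list alone, 3 and 3 with the block), and the list did not pass camera (adjusted p = 0.63). tnni1b is also a member of the heart field list, so its fall cannot be assigned to slow muscle. The summed smyhc genes were at 442 ± 78.1 CPM, a log2 fold change of -0.34 (adjusted p = 0.709), and the summed fast myosin heavy chain genes at 0.56 ± 0.142 CPM (log2 fold change -0.15, adjusted p = 0.97). Of 40 pan-muscle genes, 4 fell and 0 rose (12 and 3 adjusted over the list alone, 13 and 3 with the block). They were the actin genes acta1b at -1.71 (SE 0.19, adjusted p = 0.00155) and actc1b at -0.78, the acetylcholine receptor gene chrna1 at -1.38 and the junctophilin gene jph2 at -1.97. Camera passed these 40 genes (adjusted p = 4.33e-06) but not with an estimated correlation (adjusted p = 0.35). Of 23 myogenic regulators, 2 fell and 0 rose (3 and 0 adjusted over the list alone, 7 and 1 with the block), namely myog, the myogenin gene, from 30 to 11.2 CPM (log2 fold change -1.42, SE 0.20), and lbx1b at -1.67. This list passed camera (adjusted p = 0.00393) but not with an estimated correlation (adjusted p = 0.464). In the heart field list, 4 of 16 genes fell and 1 rose (5 and 2 adjusted over the list alone, 6 and 3 with the block). The sarcomere genes vmhc at -2.91, tnnt2a at -2.25 and tnni1b fell, as did the transcription factor gene tbx5a at -1.96, while tbx20 rose by 0.68. This list did not pass camera (adjusted p = 0.0708).

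Of 22 p53 and DNA damage response genes, 9 rose and 0 fell (14 and 1 adjusted over the list alone, 15 and 3 with the block), and the median log2 fold change was 1.33. phlda3 rose by 2.72 (SE 0.43), sesn1 by 1.37 to 1.44 within the sets (SE of the pooled value 0.19) and tp53inp1 by 1.51, all known p53 targets, and casp8, an initiator caspase gene of the list, by 2.66. Camera passed the p53 list (adjusted p = 1.39e-10) but not with an estimated correlation (adjusted p = 0.192). Of 35 cell cycle genes, 3 fell and 0 rose (21 and 0 adjusted over the list alone, 26 and 0 with the block), the replication licensing genes mcm5 at -0.78 (SE 0.12), mcm3 at -0.62 and mcm4 at -0.65. Camera passed the cell cycle list (adjusted p = 2.66e-14) but not with an estimated correlation (adjusted p = 0.0799). Other genes that rose included atxn1b at 3.19, RBL2, a retinoblastoma-family gene, at 3.14, loxl4 at 3.11, rspo1, a Wnt agonist gene, at 3.08, RNF213 at 2.68 and lnx1 at 2.55. Others that fell included gsx1, a neural homeobox gene, by 2.69 on the log2 scale, lcp1, a leukocyte plastin gene, by 2.56, cfdl by 2.47 and EFCAB6 by 2.46.

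The remaining lists held 0 or few calls without the block. In the tailbud and segmentation clock list cdx1a fell to 2.85 CPM and wnt8a (ENSDARG00000052910) rose by 0.69 (2 higher and 3 lower of 24 adjusted over the list alone, 3 and 4 with the block). In the neural crest list kita rose by 0.71, in the endothelium list aplnrb rose by 0.71, and in the Rohon-Beard list neurog1 fell by 0.67 on the log2 scale, each the 1 called member of 17, 18 and 19 genes and of the count adjusted over the list alone. With the block the neural crest list had 1 higher and 3 lower, the endothelium list 1 higher and 2 lower, and the Rohon-Beard list 2 lower. The placode list had stm at -0.61 (1 of 15 called, 2 higher and 1 lower adjusted over the list alone, 5 higher and 2 lower with the block), the FGF target list dusp4 at -0.56 (1 of 14 called, 1 adjusted over the list alone, 1 higher and 4 lower with the block) and the epidermis list tp63 at -0.51 (1 of 23 called, 4 lower adjusted over the list alone, 8 lower with the block). Camera passed the endothelium list (adjusted p = 0.0391, 0.0878 with the block) and the epidermis list (adjusted p = 0.039) but not with an estimated correlation (adjusted p = 0.698 and 0.678). Without the block no member was called, over all genes or adjusted over the list alone, in the notochord, hatching gland, blood, endoderm, Hedgehog target or ribosomal protein lists, whose medians were -0.09, 0.07, -0.16, -0.02, 0.01 and -0.06. With the block, in the same order, 0, 2, 1, 1, 1 and 0 members were higher and 3, 0, 2, 1, 2 and 8 lower, and the ribosomal protein list passed camera only with the block (adjusted p = 0.0128), and not with an estimated correlation (adjusted p = 0.946, 0.83 with the block). Among 13 reference genes 0 were called (1 lower adjusted over the list alone, 1 higher and 4 lower with the block), and among 13 interferon response genes 0 were called (1 higher adjusted over the list alone, 3 higher with the block). In all, 260 genes were called in edgeR's test, 100 higher and 160 lower, and 3203 with the block (1400 higher, 1803 lower). Scaling by library size alone gave 136 higher and 129 lower. Without the control of set A, B or C the count was 122, 168 and 78, without the morphant of set A, B or C it was 157, 99 and 109. Of the 54 named genes called, 21 kept their call without each library, among them egr2b, mafba, srl, atp2a1, acta1b, myog, sesn1 and pbx2. The call of MYH7B, actc1b, dusp4, jph2, kita, mcm4, neurog1 and stm was lost whichever library was left out, with an adjusted p of up to 0.217, and that of mdm2 without the control of set A or C. These fits had no block, and all 54 kept their call with the block fitted to all 12 libraries.

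**Figure D3:**
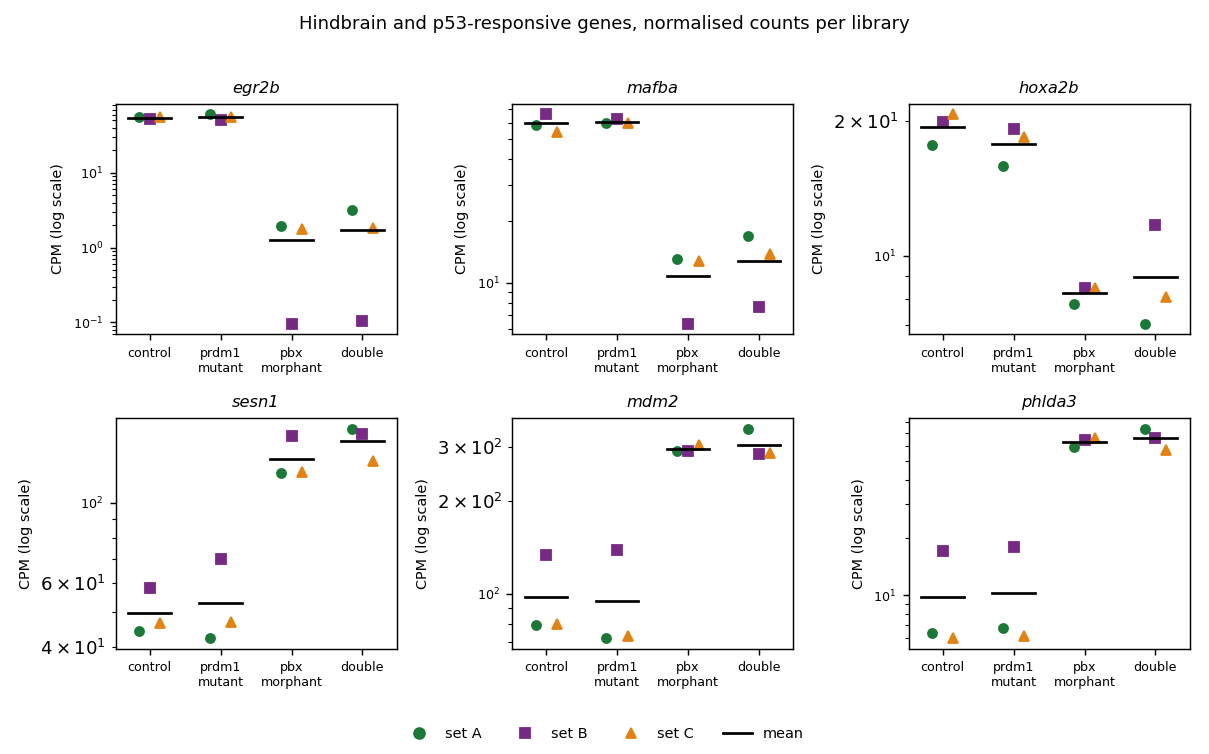
Normalised counts (CPM), on a logarithmic y axis, of egr2b, mafba and hoxa2b (first row) and of the p53-responsive genes sesn1, mdm2 and phlda3 (second row) in each library, by group, with point shape and colour for the column-name set and a line at the mean of 3 libraries. The means of egr2b are 54.8 and 55.9 CPM in controls and prdm1 mutants and 1.27 and 1.72 CPM in pbx2/4 morphants and double embryos.

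The comparison of double embryos with controls asked what loss of prdm1 and the pbx2/4 morpholinos change together. Summed slow myosin RNA was lower than in controls and summed fast myosin RNA higher. The summed smyhc genes were at 60.2 ± 12.7 CPM in double embryos (SD, n = 3), 9.29-fold below controls (log2 fold change -3.22, SE 0.28, edgeR adjusted p = 0.000138), and also below prdm1 mutants (log2 fold change -1.23, SE 0.26, adjusted p = 0.0427). The summed fast myosin heavy chain genes were at 8.48 ± 3.80 CPM, 13.6-fold above controls (log2 fold change 3.77, SE 0.47, adjusted p = 0.00189) and below prdm1 mutants (log2 fold change -1.61, SE 0.35, adjusted p = 0.046). In sets A, B and C the slow sum was 170.5, 82.6 and 169 CPM in prdm1 mutants and 46.25, 71.3 and 62.95 CPM in double embryos, so it differed little in set B. Of the 3 smyhc genes, smyhc1 was called against prdm1 mutants without the block and all 3 with it.

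Of 15 slow muscle genes, 6 fell and 2 rose (8 and 3 adjusted over the list alone). smyhc1, smyhc2 and smyhc3 had -3.22, -3.20 and -3.15, tnnt2c -1.16, myh7bb -1.91 and tnni1b, which is also in the heart field list, -2.52. In contrast, mybpc1, a slow myosin-binding protein gene, rose from 0.645 to 6 CPM (log2 fold change 3.13, SE 0.59) and MYH7B rose by 1.26. The list passed camera (adjusted p = 5.71e-06) but not with an estimated correlation (adjusted p = 0.0901). Of 25 fast muscle genes, 4 rose and 2 fell (5 and 3 adjusted over the list alone, 7 and 4 with the block), with myhz1.3 at 4.22, myhz1.1 at 4.42, myhz1.2 at 4.16 and myl1 at 1.57 higher, and srl at -1.84 and the actinin gene actn3a at -1.06 lower. The list did not pass camera (adjusted p = 0.099). Of 40 pan-muscle genes, 11 fell and 2 rose (17 and 2 adjusted over the list alone, 19 and 2 with the block), with acta1b at -1.70, chrna1 at -1.81 and xirp1 at -1.33 lower and unc45b, a myosin chaperone gene, at 0.65 higher. Camera passed the pan-muscle list (adjusted p = 1.2e-08) but not with an estimated correlation (adjusted p = 0.205). Of 23 myogenic regulators, 3 fell and 0 rose (6 and 2 adjusted over the list alone, 9 and 3 with the block), namely eya1 at -0.72, myf6 at -2.50 and lbx1b at -1.41. Camera passed the list (adjusted p = 0.0045) but not with an estimated correlation (adjusted p = 0.47).

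Of 19 Rohon-Beard and sensory neuron genes, 4 fell and 0 rose (12 and 0 adjusted over the list alone, 13 and 0 with the block), with isl1 at -1.10, the homeobox genes drgx at -1.92 and tlx3b at -1.84, and the neuronal RNA-binding protein gene elavl4 at -1.86. The list passed camera (adjusted p = 3.47e-09) but not with an estimated correlation (adjusted p = 0.0532). The hindbrain list had 9 lower and 0 higher of 37 (17 and 1 adjusted over the list alone, 19 and 1 with the block), with egr2b at -4.94, mafba at -2.21, cyp26b1 at -3.12 and dbx1b at -1.34, and camera adjusted p = 1.65e-10. With an estimated correlation it had adjusted p = 0.012 without the block but 0.132 with it. The Hox 1 to 4 list had 5 lower of 14 (7 adjusted over the list alone, 9 with the block), with hoxa3a at -1.06, and passed camera (adjusted p = 1.16e-08) but not with an estimated correlation (adjusted p = 0.0651). In the forebrain, midbrain and eye list 7 of 28 fell and 1 rose (11 and 3 adjusted over the list alone, 15 and 4 with the block), with rx1 at -1.29 and foxg1a at -0.88. In the heart field list 6 of 16 fell and 1 rose (8 and 2 adjusted over the list alone and also with the block), with vmhc at -4.40 and tbx5a at -2.27. Both passed camera (adjusted p = 6.6e-05 and 0.00208) but not with an estimated correlation (adjusted p = 0.0543 and 0.175). The p53 list had 10 higher and 0 lower of 22 (14 and 1 adjusted over the list alone, 15 and 2 with the block), a median of 1.42, with phlda3 at 2.78 and mdm2 at 1.64. It passed camera (adjusted p = 6.38e-11) but not with an estimated correlation (adjusted p = 0.185). The cell cycle list had 2 lower and 0 higher of 35 (17 and 0 adjusted over the list alone, 27 and 0 with the block), with mcm5 at -0.79, camera adjusted p = 3.98e-12 and, with an estimated correlation, adjusted p = 0.098. agr2, at 111 ± 55 CPM, and p2rx1, at 6.8 CPM, were again higher than in controls, by 4.93 and 4.63 on the log2 scale.

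In all, 407 genes were called in edgeR's test of double embryos against controls, 151 higher and 256 lower, and 3655 with the block (1691 higher, 1964 lower). Scaling by library size alone gave 194 higher and 219 lower. Without the control of set A or C the count was 197 and 163, without the double library of set A, B or C it was 188, 218 and 267. Of the named genes, 42 of the 65 called kept their call without each of the 6 libraries, and actn3a, dusp4 and hoxc1a lost it whichever was left out, with an adjusted p of up to 0.178. No block was used in these fits, and with the block fitted to all 12 libraries all 65 kept their call.

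**Figure D4:**
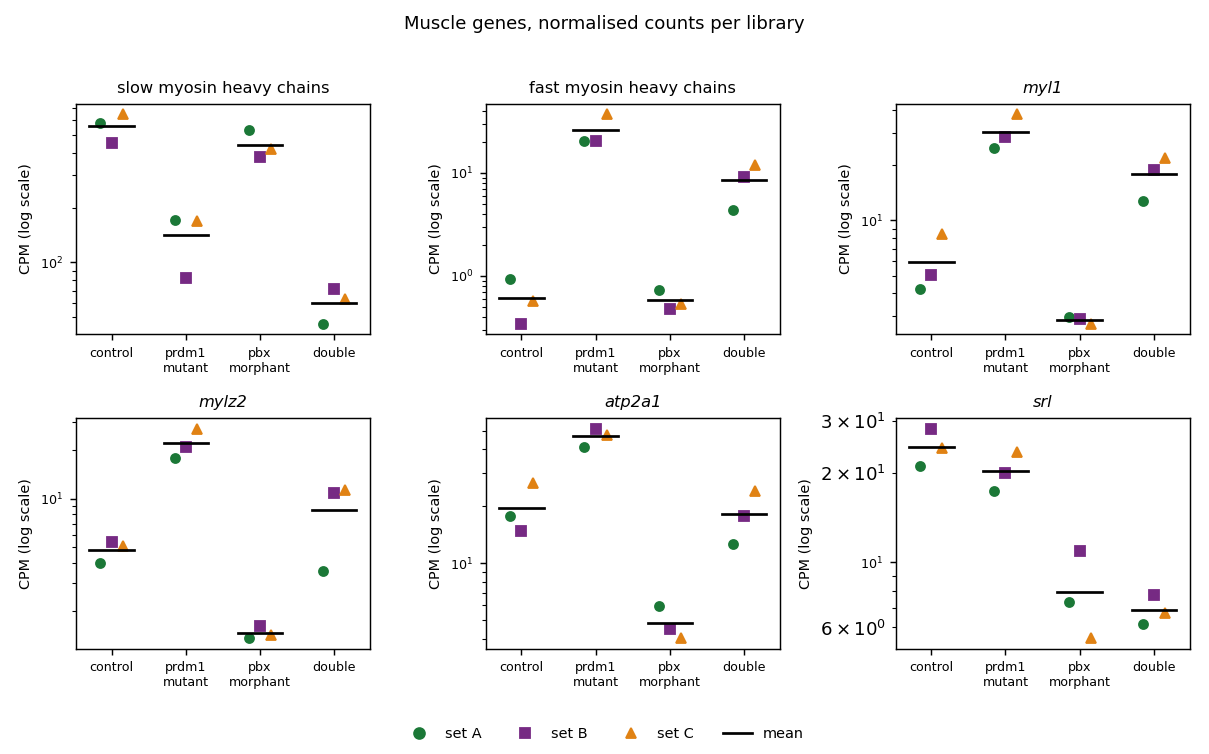
Normalised counts (CPM), on a logarithmic y axis, of the summed slow and fast myosin heavy chain genes and of myl1, mylz2, atp2a1 and srl in each library, by group, with point shape and colour for the column-name set and a line at the mean of 3 libraries. The fast myosin heavy chain sum averages 0.626 CPM in controls, 26 in prdm1 mutants, 0.56 in pbx2/4 morphants and 8.48 in double embryos.

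The comparison of double embryos with prdm1 mutants asked what the pbx2/4 morpholinos change where prdm1 is lost. srl fell from 20.3 to 6.88 CPM (log2 fold change -1.57, SE 0.23, edgeR adjusted p = 0.00557) and atp2a1 from 46.7 to 18.1 CPM (log2 fold change -1.36, SE 0.25, adjusted p = 0.0206). These were the 2 fast muscle genes of 25 that fell, with 0 that rose (8 and 0 adjusted over the list alone, 12 and 1 with the block). It passed camera (adjusted p = 0.00045) but not with an estimated correlation (adjusted p = 0.167). mylz2 had -1.37 and myl1 -0.77, called only with the block and named here after their values were seen. In the slow list 2 of 15 fell and 1 rose (5 and 1 adjusted over the list alone, 5 and 3 with the block), with smyhc1 at -1.25, tnni1b at -2.80 and MYH7B at 1.23. Here too tnni1b is shared with the heart field list. The log2 fold change of smyhc1 was -1.89, -0.24 and -1.43 within sets A, B and C. Its call was lost without the prdm1 mutant of set A or C and without the double library of set A, B or C, with an adjusted p of up to 0.19. In the pan-muscle list 3 of 40 fell and 1 rose (9 and 1 adjusted over the list alone, 11 and 2 with the block), acta1b from 51.3 to 19.4 CPM, chrna1 at -1.73, the titin gene ttna at -1.25 and unc45b at 0.53. Camera passed the list (adjusted p = 0.000146) but not with an estimated correlation (adjusted p = 0.492). Of the myogenic regulators, lbx1b at -1.52 and myog at -0.98 fell, and 0 of 23 rose (3 lower and 1 higher adjusted over the list alone, 6 and 2 with the block).

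Outside muscle, egr2b at -4.96, cyp26b1 at -3.04, mafba at -2.24 and hoxa3a at -1.15 fell, and sesn1 at 1.49, mdm2 at 1.69 and phlda3 at 2.72 rose. The hindbrain list had 10 lower and 0 higher of 37 (16 and 1 adjusted over the list alone, 18 and 1 with the block), with camera adjusted p = 5.44e-14. With an estimated correlation the adjusted p was 0.00824 without the block but 0.0763 with it. The p53 list had 11 higher and 0 lower of 22 (15 and 1 adjusted over the list alone, 15 and 2 with the block), and passed camera (adjusted p = 1.21e-12) but not with an estimated correlation (adjusted p = 0.152). Of 19 Rohon-Beard and sensory neuron genes 0 were called, over all genes or adjusted over the list alone, and 2 were lower with the block. In all, 247 genes were called in edgeR's test, 100 higher and 147 lower, and 2935 with the block (1308 higher, 1627 lower). With scaling by library size alone 124 were higher and 122 lower. The count was 88 and 72 without the prdm1 mutant of set A or C and 104 and 127 without the double library of set A or B. Of the 40 named genes called, 19 kept their call without each of the 6 libraries, atp2a1 kept it only without the double library of set C, and hoxc1a lost it whichever was left out. With the block fitted to all 12 libraries, all 40 kept their call.

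The comparison of double embryos with pbx2/4 morphants asked what loss of prdm1 changes in embryos with pbx2/4 morpholinos. The summed fast myosin heavy chain genes were higher in double embryos (log2 fold change 3.92, SE 0.47, edgeR adjusted p = 0.00323), and the summed smyhc genes 7.34-fold lower (log2 fold change -2.88, SE 0.28, adjusted p = 0.000558). agr2 was higher by 5.65, p2rx1 by 4.42, myl1 by 2.64, mylz2 by 2.54 and atp2a1 by 1.92 on the log2 scale, prdm1a by 0.90 (SE 0.11, adjusted p = 0.00254), and isl1 had -1.14, drgx -2.24 and slc4a4a -1.21. Except prdm1a, these genes were picked after their values in this comparison were seen. In all, 27 genes were called in edgeR's test, 12 higher and 15 lower, and 218 with the block (128 higher, 90 lower). The count was 17 without the pbx2/4 morphant of set C.

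The interaction contrast asked whether the effect of prdm1 loss differs between embryos with and without pbx2/4 morpholinos. No gene was called of 18117 (26607 in DESeq2) in edgeR's quasi-likelihood test, in its likelihood ratio test, in DESeq2 or with the block. In that order, 103, 107, 96 and 523 genes had an unadjusted p under 0.05. Chance alone would give a share of 0.05 of the genes tested, and each count lies below it. These tests were thus conservative, and the absence of calls does not exclude interactions. The interaction was -1.46 (SE 0.72, adjusted p = 1) on the log2 scale for the summed fast myosin heavy chain genes and -0.89 (SE 0.37, adjusted p = 1) for the summed smyhc genes. For prdm1a it was 0.49 (SE 0.15, adjusted p = 1). The planned adjustment was over all genes tested. By it prdm1a was called in 0 of 25 alternative settings, the block included, with a lowest adjusted p of 0.0808. Adjusted instead over the 8 tested rows of prdm1 and pbx genes alone, the edgeR p was 0.0518 without the block and 0.00018 with it. That narrower adjustment does not establish an interaction for prdm1a.

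The overlap of the comparisons of prdm1 mutants and pbx2/4 morphants, which share their controls, was counted per direction. No gene was called in both in edgeR's test, where independent lists would give 0.0828 genes higher in both and 0.177 lower in both. DESeq2 called 3 genes in the same direction in both, for which no value of independent lists was computed. With the block, 10 were higher in both, 25 lower in both and 14 opposite, against 6.88, 10.9 and 17.4 for independent lists and 0.075, 0.025 and 0 in 40 simulations of unchanged groups against the same controls. Unchanged groups hold almost no calls, so the simulated overlap was small by construction and cannot gauge the observed one. Among the genes of opposite direction with the block were the fast muscle genes myl1, at 2.35 in mutants and -1.08 in morphants, mylz2, at 2.22 and -1.72, and atp2a1, at 1.24 and -2.05. Genes lower in both included MYL4, at -1.92 and -0.83, and tnnt2c, at -0.98 and -0.43. These 5 genes were picked as examples after their values were seen. The log2 fold changes correlated at 0.165 across genes, below the 0.521 of the simulations, and their covariance was 0.0231 against 0.0283 simulated. In unchanged groups the correlation comes from the shared controls alone, and unrelated real effects in either group dilute it. The lower observed correlation alone therefore does not show a lack of shared effects. Such dilution would not lower the covariance, which differed from the simulated mean by -0.0052 (-0.0047 with the block). The covariance thus gave no sign of a net shared effect in the same direction over all genes. The cause of its lower value was not tested. The 3 controls cannot be parted into groups of at least 2 libraries each, so part of any excess over independent lists may come from the shared controls.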

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

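No test in this part was chosen after a result was seen. The effect of prdm1 loss differed between embryos with and without pbx2/4 morpholinos for 2 of the 27 gene lists when the difference itself was tested by camera with a preset correlation. For the myogenic regulators the median difference was 0.11 on the log2 scale (adjusted p = 0.039), and for the endothelium list it was also 0.11 (adjusted p = 0.0202). Neither held with an estimated correlation (adjusted p = 0.633 and 0.639), and with the block the values were 0.0693 and 0.0188. No single member of either list was called in the edgeR test of the interaction. There 103 of 18117 genes had an unadjusted p under 0.05, fewer than the share of 0.05 that chance alone would give. No technical or biological explanation was tested for these differences. Groups of 3 libraries are too small for the test of single outlying libraries, which was not run.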

How the results depend on the processing

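Leaving out all 4 libraries of a set, the block with DESeq2, the block with a fold of at least 1.5 and counts without rounding were chosen after the data were seen. No named gene called without the block changed sign in any alternative, while some that were not called did, such as pbx1a (ENSDARG00000089550) in double embryos against controls, from -0.08 to 0.73, and pbx3b there, from -0.52 to 0.12. Over single genes and settings, 3081 values kept their side of the threshold, 529 lost and 110 gained a call, and with 1 library left out 1255 kept it, 393 lost and 2 gained it. Of the 529 losses, 180, 78 and 182 came from leaving out set A, B or C in the fit without the block. Over lists 266 values kept their side of the threshold, 54 lost and 4 gained a call. Counts of called genes are given in the order prdm1 mutants, pbx2/4 morphants and double embryos against controls, then double embryos against prdm1 mutants and against pbx2/4 morphants, from 35, 260, 407, 247 and 27. DESeq2 gave 63, 546, 713, 550 and 66, and edgeR's likelihood ratio test 76, 496, 694, 487 and 75. The replicate block gave 199, 3203, 3655, 2935 and 218, among them all of the genes called without it, and the biological coefficient of variation fell from 0.212 to 0.075. The block with DESeq2 gave 211, 2243, 2573, 2120 and 208, and the block with a fold of at least 1.5 gave 137, 1127, 1420, 1034 and 149. With only the 6 libraries compared the counts were 18, 120, 205, 95 and 15. Leaving out 1 library gave ranges of 14 to 23, 78 to 168, 163 to 311, 72 to 196 and 17 to 23. In the fit without the block they were 0, 1, 9, 1 and 1 without the 4 libraries of set A. Without set B they were 22, 108, 247, 153 and 20, and without set C 2, 0, 2, 0 and 2. With the block and without set A, B or C, 14, 14 and 15 of 22 p53 genes were higher in pbx2/4 morphants than in controls. There 2, 3 and 2 were lower. Of 35 cell cycle genes 21, 23 and 21 were lower in that comparison and 0 higher. The interaction gave 0 genes in each setting that holds all 4 groups. Of the tests of gene lists, 52 passed with the preset correlation, 7 with an estimated correlation and 33 in fry. Genes shared in direction by prdm1 mutants and pbx2/4 morphants numbered 0 without the block, 3 in DESeq2 and 35 with the replicate block. The cause of these changes was not tested. At these depths 1 count corresponds to 0.058 to 0.11 CPM, which limits genes such as myhz1.1 and myf6.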

Other observations

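For the p53 list, the checks of set, scaling and morpholino effect were chosen only after the results were seen. The same holds for the checks of delay and of muscle tissue in pbx2/4 morphants. The counts of called list members and the camera tests were planned. agr2 and p2rx1, which rose in prdm1 mutants and in double embryos, had whole-number counts in all 12 libraries. Of 25 fast muscle genes, 9 had a positive log2 fold change in prdm1 mutants and a negative one in pbx2/4 morphants, and 3 of these were called in both with the block.

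Genes called with the block in prdm1 mutants were more frequent among the neighbours of prdm1a. Up to 200 genes on either side were taken, in gene order of another assembly. The window held 268 genes because it reached an end of the chromosome, so its genes need not lie close to prdm1a. Of these, 14 of 268 were called against 158 of 13883 elsewhere, an odds ratio of 4.79 (95% interval 2.52 to 8.42, two-sided Fisher's exact p = 4.99e-06). Of the 198 called genes other than prdm1a, 86.9% could be placed, and without the block 0 of 268 and 28 of 13883 were called, with an upper limit of 7.33. Variants linked to the mutant prdm1a allele may therefore contribute to calls such as icn (0.91) and gapdh (0.51). Among the 14, echdc1 (4.45) and HPX (2.04) rose most and stmn2a (-1.98) fell most, named here after their values were seen. stmn2a is a member of the Rohon-Beard list, so the result of that list includes it. echdc1 was also higher with the block in pbx2/4 morphants, which are prdm1+/+, by 3.11 on the log2 scale. Regulation of neighbours by Prdm1 was not tested and stays open, since no marker of the linked strain is in these files.

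Of 22 p53-responsive genes, without the block 9 were higher in pbx2/4 morphants and 10 in double embryos against controls, but the list did not pass camera with an estimated correlation (adjusted p = 0.192 and 0.185). A single set as source is argued against by the lowest of the 6 medians of the list, 0.78, and library scaling by the lowest median under other scalings, 1.33. The median for the pbx2/4 morpholinos in prdm1-/- embryos was 1.37. An effect of the morpholinos apart from pbx loss and an effect of pbx loss cannot be told apart, because no group carries a pbx mutation or a second morpholino pair.

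In pbx2/4 morphants 4 of 40 pan-muscle and 2 of 25 fast muscle genes were lower without the block, while the pan-muscle list failed camera with an estimated correlation (adjusted p = 0.35) and the fast and slow lists failed it with the preset correlation (0.0737 and 0.63). A delay of the whole embryo may lower them. The hatching gland genes he1a, he1b and wu:fa26c03 had a mean log2 fold change of 0.20 (SD 0.14 over the 3 sets, 0.05 to 0.32) against a pan-muscle median of -0.29. These 3 genes belong to another tissue than muscle, and he1a was itself called higher with the block (0.30). They therefore cannot exclude a delay. Less muscle tissue, as the whole cause, would lower every muscle gene. Of 65 members of the fast and pan-muscle lists 6 rose and 22 fell with the block (one-sided exact binomial p = 0.00227 against a share of 0.05 false calls). This cannot decide, because the threshold bounds false calls over all genes and not within a list, and members are not independent. Of all 18117 genes, 1400 were called higher and 1803 lower with the block. Without set A, B or C, 1, 2 and 1 fast muscle genes rose with the block and 6, 9 and 5 fell. In the pan-muscle list these counts were 2, 2 and 2 higher and 11, 12 and 8 lower. Less muscle tissue, as the whole cause or a part, stays open. Whether pbx loss or another effect of the morpholinos lowers these genes was not tested, since no group carries a pbx mutation or a second morpholino pair.

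The 10 splits of 6 libraries are too few for a share under 0.05. They were fitted without the block, and 4 of them, the real split included, part the libraries of every set. The others mix differences between sets into the groups. The real split gave 35, 260, 407, 247 and 27 called genes in the comparisons against controls (prdm1 mutants, pbx2/4 morphants, double) and of double embryos against prdm1 mutants and pbx2/4 morphants, and the highest other split gave 0 in each, so 1 of 10 splits reached the real count. For the interaction the real count was 0, so that 50 of 50 regroupings reach it by construction and their number tests nothing. The highest gave 97, and it exchanges all labels of pbx2/4 morphants and double embryos, so that it measures the effect of prdm1 loss.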
